A study of Oryza sativa Japonica Group with 21 samples.

How the data were processed

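RNA from rice (Oryza sativa japonica, cultivar Zhonghua 15) was measured on 21 Affymetrix rice arrays in 7 groups of 3. There were 2 leaf groups, the primordium of leaf 3 and the just-expanded leaf 3, and 5 stamen groups, stages 2, 3, 4, 5 and 6. Per the labels, leaf primordia were dissected from embryos of seeds soaked for 2 to 3 days, and stamens were dissected from spikelets. Plants grew at 30 ± 2 °C with 11 h of light and 13 h of dark, in pots or in the field, and the labels do not say which applied to which sample. From 50 to 300 ng of total RNA was amplified through 2 cycles before labelling with biotin.

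The authors deposited log2 values per probe set made with RMA (background correction, quantile normalization and summary). The version of RMA is not given in the sources used here. Medians of the arrays lay between 5.82 and 5.88, and no 2 arrays held identical values. The number of arrays per group limits the precision.

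The table held 57381 probe sets, of which 123 control probe sets were left out and 57258 were tested, 64 reporter probe sets among them. An annotation of assembly ASM3414082v1 gave 1 gene for 22436 probe sets, several for 95 and none for 34727, with 17905 genes in all. It served for gene names only, so no positions are given. Of these genes, 2451 had an informative name.

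One limma model (limma 3.58.1, R 4.3.3) was fitted to all 21 arrays with 7 group means. From it came 8 comparisons: the mean of the 5 stamen stages against each leaf sample, expanded leaf against leaf primordium, each stage against the one before, and stage 6 against stage 2. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Change over the stages was tested with limma's F test and a 2-fold range of stage means. Probe sets above or below both leaf samples were called by the larger of 2 one-sided p-values. All tests of single comparisons were two-sided. Each stage was also set against each leaf sample for OsMADS58 and for the gene lists described below.

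Gene lists were tested with camera (in limma) against all other genes at a preset correlation of 0.01, with 1 probe set per gene, the one with the highest mean. Camera with an estimated correlation and fry were alternatives. Adjustment was over the 19 lists within a comparison. The lists, with 228 members in all, were fixed from gene symbols before the data were examined, as were the comparisons, the thresholds and the alternatives, apart from the 3 named last and the method of the array weights. They were floral MADS-box genes, carpel and ovule markers, early anther cell fate, late tapetum and pollen wall, meiosis, mitotic cyclins and B-type CDK, DNA replication, H2B histones, cytosolic ribosomal proteins, photosynthesis light reactions, Calvin cycle, chlorophyll synthesis, chloroplast regulators, auxin signalling, expansins, lipid transfer proteins, heat shock proteins, embryo and seed reserve markers, and meristem and organ polarity regulators. Symbols the annotation did not list were left out.

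The genes named in the text followed a rule. It took the 8 largest rises and falls of each broad comparison and the 4 largest of each pair of consecutive stages, among called probe sets with a named gene and no overlap between the arrays compared. It always took OsMADS58 and the members of the floral MADS-box, carpel, early anther, meiosis, late tapetum and chloroplast regulator lists, and up to 4 called members of any other list. Not every gene the rule took is named.

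RNA quality was read from the control probe sets at the 3' and 5' ends of actin and GAPDH. The mean of their 3' minus 5' log2 differences is called the 3' to 5' difference. The ubiquitin and cyclophilin pairs were left out of it. Ubiquitin was also higher at stage 2 (-0.48 to -0.25) than at stage 6 (-1.52 to -1.15), but cyclophilin overlapped (2.37 to 2.76 and 1.89 to 2.57). In expanded leaf, cyclophilin was 0.98 in replicate 3, between replicate 1 (-0.1) and replicate 2 (1.35).

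The alternatives were quantile normalization or median centring of the deposited values, filters on dim probe sets, a variance prior with trend and robust fitting, array weights (gene-by-gene method), the replicate number as a block, only the groups compared, no fold threshold, an adjusted p under 0.01, the mean of each gene's probe sets, and leaving out each array in turn. Chosen after the values were seen were the 3' to 5' difference as a covariate, and fits without the expanded leaf arrays or without the stage 2 arrays. The model was tested on simulated data built from these arrays. Of 100 probe sets given a log2 change of 1.5, it recovered 86 for stage 6 against stage 2 and 90 for stamen against leaf primordium. The simulated noise was normal and independent between probe sets, with the same spread in all groups. It held no array or 3' bias effect, so these shares say nothing of such effects.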

Results

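Gene expression was measured in stamens at 5 early stages of development and in 2 leaf samples, with 3 arrays per group. The leaf samples served the authors as controls, since stamen and leaf are homologous organs. Arrays of 1 group correlated at r = 0.981 to 0.995 in leaf primordium, 0.984 to 0.995 in the stamen groups and 0.931 to 0.949 in expanded leaf, over all probe sets. Stamen arrays correlated with leaf primordium at 0.902 to 0.925 and with expanded leaf at 0.786 to 0.829. Arrays of different stamen stages correlated at 0.955 to 0.994, so the stages overlapped. The stage 3 replicates 1, 2 and 3 were closer to a stage 4 array (0.992, 0.988 and 0.992) than to their own replicates (at most 0.989, 0.985 and 0.989). Stage 4 replicate 1 and stage 5 replicate 3 were also closest to an array of another stage.

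Stamens were set against leaf primordium, which came from embryos of soaked seeds. The genes that set floral organ identity were far higher in stamens. OsMADS8 stood at 12.80 ± 0.32 (log2, SD, n = 15) in stamens and 4.59 ± 0.07 (n = 3) in leaf primordium, a difference of 8.21 (SE 0.106, adjusted p = 2.8e-18 by limma). OsMADS16, a B-class gene, was higher by 7.80, and OsMADS7 by 7.43. Of the 15 floral MADS-box genes 13 were higher, OsMADS17 was lower (-1.07, under 2-fold without leaf primordium replicate 2) and OsMADS15 was not called (0.40). The list's median difference was 3.36 (adjusted p = 4.11e-09, and 0.00255 with an estimated correlation).

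Genes of cell division went the same way. In leaf primordium the mitotic ones lay near their expanded leaf level, with 0 of 8 called between the 2 leaf samples. All 8 mitotic cyclins and B-type CDK genes were higher, among them CYCB2-2 by 7.81 and CYCB1-1 by 6.64, with a list median of 5.23 (adjusted p = 1.62e-08, and 0.00255 with an estimated correlation). Of 19 DNA replication genes 13 were higher, 1 was lower and 5 were not called. MCM3, part of the replicative helicase, was higher by 6.14 (list adjusted p = 1.99e-07, but adjusted p = 0.118 with an estimated correlation). Of the 5 H2B histones 4 were higher (adjusted p = 0.022, and adjusted p = 0.209 with an estimated correlation), 2 of which fell under 2-fold without leaf primordium replicate 3.

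Some genes of anther and germ cell development were also higher. MSP1, a receptor kinase that limits the number of sporogenous cells, was higher by 3.41. The transcription factor gene BHLH142 was higher by 4.72 and MEL1, a germline Argonaute, by 4.69. Of the 5 early anther genes 3 were higher and 2 were not called (adjusted p = 0.0205, and adjusted p = 0.118 with an estimated correlation), with 1 higher at stage 2 and 3 at stage 3, where the list did not pass (adjusted p = 0.259 and 0.122). Of the 7 meiosis genes 5 were higher (PAIR2 under 2-fold without leaf primordium replicate 1) and 2 were not called (adjusted p = 0.0205, and adjusted p = 0.124 with an estimated correlation), and neither list was called among only the probe sets above the median mean.

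Among the largest falls from leaf primordium to stamen were OsPP2C45, a protein phosphatase (-8.12), and genes of seed desiccation. EM, a late embryogenesis abundant protein, stood at 13.97 in leaf primordium and 6.81 in stamens, LEA19 had a difference of -5.30 and RAB16C, a dehydrin, of -6.36. The leaf primordia came from soaked embryos. Over the 10 embryo and seed reserve markers 1 was higher, GLB1 (2.66), 2 were lower and 7 were not called. Their median was 0.13, their mean -0.82 and the test pointed up (adjusted p = 0.917). GLUA-1, GLUA-3 and GLUD-1 lay low in every group (3.34 to 4.11), and GLB1 and GLUA-2 were highest in expanded leaf (10.75 and 10.3). The result of this list thus says little about embryo tissue. Heat shock proteins were lower in 11 of 23 genes, higher in 1 and not called in 11 (adjusted p = 0.00452, but adjusted p = 0.278 with an estimated correlation), with HSP23.2 at -7.06. The higher one was HSP26.2, whose probe set shares its cluster number with that of the expansin gene EXPB4, so which gene it measures is in doubt. Of 4 meristem and organ polarity regulators 3 were lower and 1 was not called (adjusted p = 0.0223, and adjusted p = 0.258 with an estimated correlation), with OsYABBY5 at -4.06 and the homeobox gene OSH1 at -1.79. OSH1 stood at 8.14 in leaf primordium, 8.74 at stage 2 and 5.36 at stage 6, and at stage 2 the list had 2 lower and 2 not called (adjusted p = 0.318).

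Other lists did not pass against leaf primordium. Auxin signalling had 14 genes higher, 6 lower and 23 not called (adjusted p = 0.337), with IAA9 at -5.18. Expansins, which loosen cell walls, had 3 higher, 6 lower and 20 not called (adjusted p = 0.219). Lipid transfer proteins had 2 lower and 2 not called (adjusted p = 0.123). Cytosolic ribosomal proteins had 1 higher, RPL39C (1.02, not called when any 1 of 4 arrays was left out, with median centring or with the 3' to 5' covariate), and 19 not called (adjusted p = 0.108). Late tapetum and pollen wall genes had 1 lower (CP1, under 2-fold without leaf primordium replicate 3) and 4 not called, with median 0.02, mean -0.03 and a test pointing down (adjusted p = 0.764). None of the 3 carpel and ovule markers was called, with median 0.07, mean -0.09 and a test pointing down (adjusted p = 0.774, by camera). DL, of that list, stood at 7.89 in stamens, 8.50 in leaf primordium and 7.67 in expanded leaf. Its level was thus alike in leaf and stamen and says little about carpel tissue.

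In all, 4348 probe sets were higher in stamens than in leaf primordium and 3841 lower. With the stamen arrays as 1 group, 7 lists were called, and another split of the same 18 arrays called 8.

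**Figure D1:**
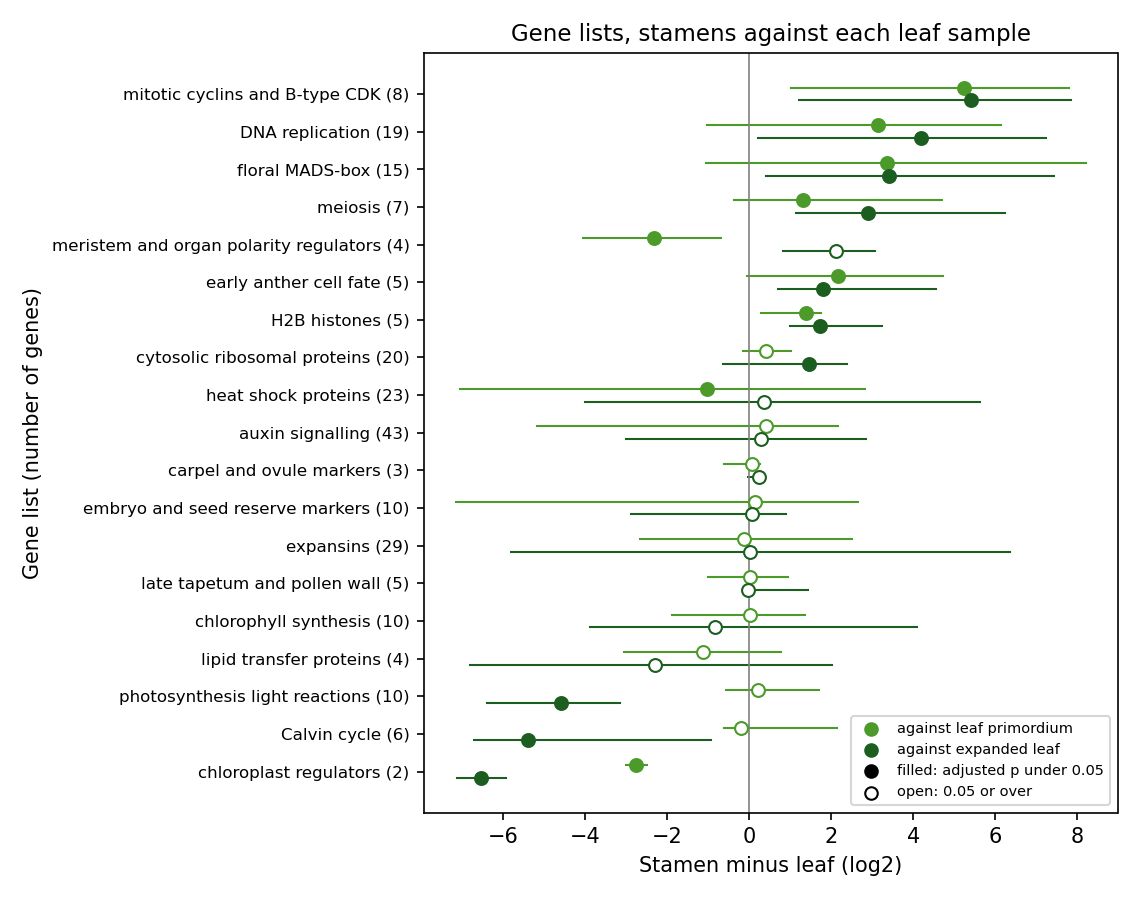
Median difference of each gene list (points) and range over its genes (lines), stamen minus leaf in log2, against leaf primordium (light) and expanded leaf (dark); filled points have an adjusted p under 0.05. The light reactions list lay at -4.60 against expanded leaf and 0.21 against leaf primordium.

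Against the expanded leaf, a mature green organ, most floral and dividing-cell genes were again higher and most photosynthesis genes were lower. OsMADS8 was higher by 7.44, CYCB2-2 by 7.85 and MCM2 by 7.16. Floral MADS-box genes were higher in 14 of 15 cases, with 1 not called (median 3.41, adjusted p = 3.87e-06, and 0.0168 with an estimated correlation). All 8 mitotic cyclins and B-type CDK genes were higher (median 5.40, adjusted p = 1.51e-05, and 0.0168 with an estimated correlation). DNA replication genes were higher in 17 of 19 cases (median 4.18, adjusted p = 1.63e-07, but adjusted p = 0.071 with an estimated correlation). All 7 meiosis genes were higher, MSH5 by 4.56 (adjusted p = 0.00191, but adjusted p = 0.0597 with an estimated correlation), though MER3 (1.40) lost its call without expanded leaf replicate 1 or replicate 2 and HEI10 fell under 2-fold without replicate 3. MSH5 was 1 of the 2 meiosis genes not called against leaf primordium. It stood at 9.33 there, 4.41 in expanded leaf and 8.85 to 9.21 at the stamen stages, so it exceeded only the expanded leaf.

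Early anther genes had 3 higher and 2 not called (adjusted p = 0.0328, and adjusted p = 0.13 with an estimated correlation). That list was not called without expanded leaf replicate 2 (adjusted p = 0.0543, early anther cell fate, stamen minus expanded leaf), or among only the probe sets above the median mean (adjusted p = 0.0748). H2B histones had 4 of 5 higher (adjusted p = 0.0165, and adjusted p = 0.16 with an estimated correlation). Cytosolic ribosomal proteins had 14 of 20 higher, RPL5A by 2.37 (adjusted p = 0.00121, but adjusted p = 0.539 with an estimated correlation).

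The largest falls included RCAA1, a Rubisco activase, whose probe sets differed in size (-9.82 and -6.73). They also included the phototropin gene Osnph1a (-7.96), the metallothionein MT2B (-8.44) and FBPase, whose probe sets gave -7.54 and -5.99. Lipid transfer proteins split into 2 higher and 2 lower (adjusted p = 0.458), with LTP at -6.82. Expansins had 11 higher, 5 lower and 13 not called (adjusted p = 0.913), with EXPA5 at 6.37 and EXPB3 at -5.82. Auxin signalling had 13 higher (14 adjusted over the list alone), 10 lower and 20 not called, with median 0.29, mean 0.15 and a test pointing down (adjusted p = 0.913). Heat shock proteins had 7 higher, among them the doubtful HSP26.2, 6 lower and 10 not called (adjusted p = 0.913). Meristem and organ polarity regulators had 3 higher and 1 not called (adjusted p = 0.217), and OSH1 lost its call without expanded leaf replicate 1 or replicate 2. Embryo and seed reserve markers had 1 lower and 9 not called, with median 0.07, mean -0.19 (adjusted p = 0.513). Late tapetum genes had 1 higher and 4 not called, with median -0.04, mean 0.34 and a test pointing up (adjusted p = 0.811). None of the 3 carpel and ovule markers was called (camera adjusted p = 0.913). In all, 7623 probe sets were higher in stamens and 5708 lower.

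Whether photosynthesis genes are held down in young stamens was the question in the study's title. In expanded leaf the median of 10 light reactions genes was 12.29 ± 1.09 (log2, SD, n = 3). It was 8.11 ± 0.30 at stage 2, 7.23 ± 0.23 at stage 3, 7.28 ± 0.23 at stage 4, 7.43 ± 0.13 at stage 5 and 7.57 ± 0.39 at stage 6. In leaf primordium it was 7.37 ± 0.08, in the range of the stamens. All 10 genes were lower in stamens than in expanded leaf, PETE, which encodes plastocyanin, by a difference of -6.40 (SE 0.193) and RCABP89, a chlorophyll binding protein, by -5.45 (SE 0.266). Their median was -4.60 (adjusted p = 7.08e-06, but adjusted p = 0.106 with an estimated correlation). Each single stage gave a median between -4.90 and -4.05 (adjusted p from 4.24e-06 to 8.04e-06, and from 0.0884 to 0.113 with an estimated correlation). Against leaf primordium 1 gene was higher, CAB2R (1.70, adjusted p = 0.0431; 0 adjusted over the list alone) and 9 were not called (list median 0.21, adjusted p = 0.764). CAB2R lost that call when any 1 of 13 arrays was left out. Its mean was 5.35 in leaf primordium, 9.24 at stage 2 and between 6.04 and 6.97 at the later stages, so its excess was largest at stage 2. Per stage, the list's adjusted p against leaf primordium ran from 0.518 to 0.971.

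**Figure D2:**
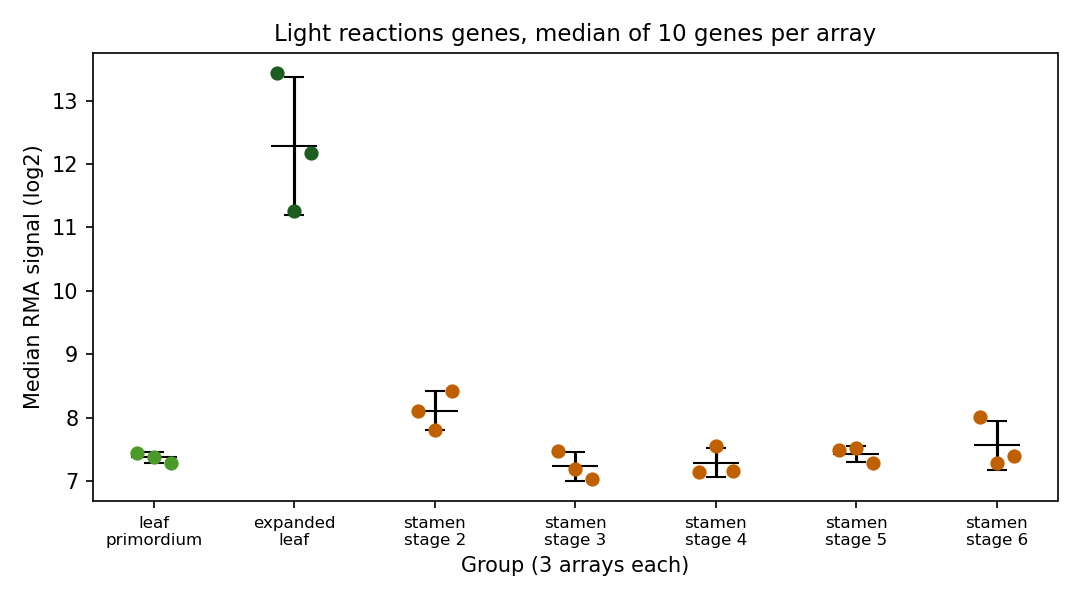
Median signal (log2) of 10 light reactions genes in each array, with the mean and SD of 3 arrays per group. The 3 expanded leaf arrays lie between 11.26 and 13.43, and leaf primordium has a mean of 7.37.

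The Calvin cycle followed: 5 of 6 genes were lower than in expanded leaf, ALDP by a difference of -6.24 and the Rubisco small subunit RBCS by -4.82 (list median -5.40, adjusted p = 4.12e-05, but adjusted p = 0.0597 with an estimated correlation). Against leaf primordium 1 was higher, RBCS (2.13), and 5 were not called, with median -0.21, mean 0.12 and a test pointing down (adjusted p = 0.764). GLK1 and GLK2, transcription factors of chloroplast development, were lower in stamens than in both leaf samples, GLK1 by a difference of -2.51 and GLK2 by 8.02-fold against leaf primordium (adjusted p = 0.0223, but adjusted p = 0.118 with an estimated correlation). Against expanded leaf their differences were -5.93 and -7.14 (adjusted p = 0.0142, but adjusted p = 0.0597 with an estimated correlation). Chlorophyll synthesis genes split, with 3 higher, 1 lower and 6 not called against leaf primordium (adjusted p = 0.917), and each of the 3 (GluTR, CHLI and CHLG) lost its call without leaf primordium replicate 1 or 3. Against expanded leaf 2 were higher, CHLH by 4.10 among them, 4 lower and 4 not called (adjusted p = 0.463), and PORB lost its call without expanded leaf replicate 1 or replicate 2.

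OsMADS58, the C-class gene in the study's title, was at 4.50 ± 0.12 (n = 3) in leaf primordium and between 10.58 and 10.89 at the 5 stages. Each stage was higher than leaf primordium by 6.08 to 6.39 (SE 0.69, adjusted p from 1.64e-06 to 2.94e-06). Against expanded leaf, at 7.36 ± 2.33 (n = 3), the differences were 3.22 to 3.53 (adjusted p from 0.000491 to 0.00113). The 3 expanded leaf arrays were at 5.76, 6.29 and 10.04, so replicate 3 lay near the stamen level, and that array's 3' to 5' difference was 3.37 where the other 2 had 1.73 and 1.96. In fits of only the groups compared, the 5 differences from leaf primordium stayed called and the 5 from expanded leaf did not.

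**Figure D3:**
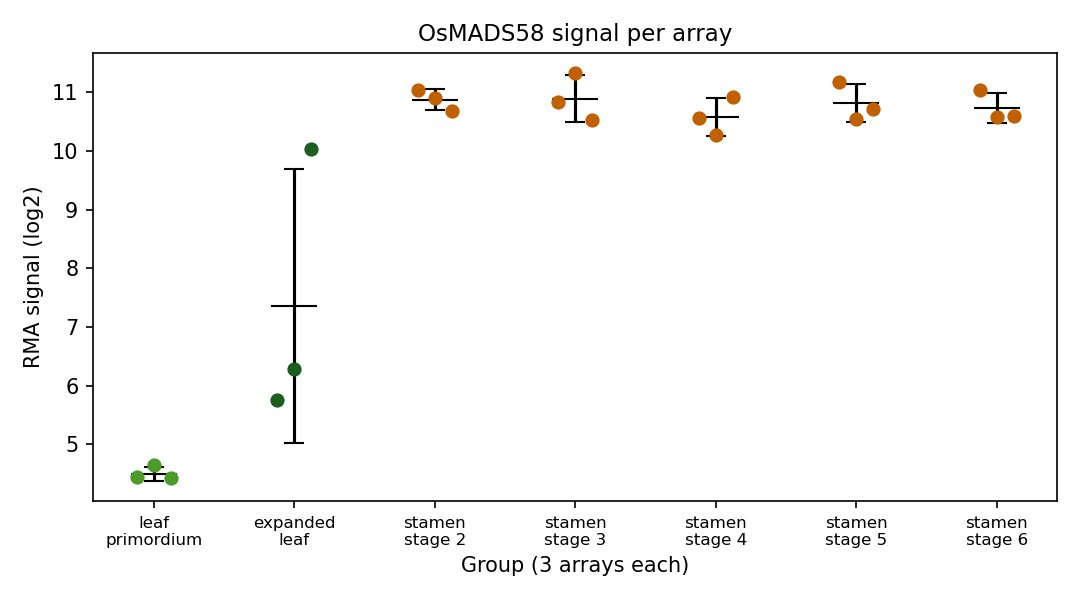
OsMADS58 signal (log2) in each array, with the mean and SD of 3 arrays per group. Leaf primordium lies near 4.50, the stamen stages have means of 10.58 to 10.89, and 1 expanded leaf array is at 10.04.

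The expanded leaf was set against its primordium as the leaf's own course of development. Photosynthesis genes were higher in the expanded leaf: all 10 light reactions genes (median 4.95, adjusted p = 8.51e-06, but adjusted p = 0.211 with an estimated correlation) and 5 of 6 Calvin cycle genes (median 5.77, adjusted p = 4.21e-05, but adjusted p = 0.211 with an estimated correlation). RCAA1 was higher by 9.27 and Osnph1a by 8.27. PDC, a pyruvate decarboxylase, was lower at -8.05, AMY1.3, an alpha-amylase, at -7.83, and EM at -7.42. DNA replication genes had 10 lower, 1 higher and 8 not called (median -1.09, adjusted p = 0.0304, but adjusted p = 0.635 with an estimated correlation), and that list, DNA replication, expanded leaf minus leaf primordium, was not called without expanded leaf replicate 1 (adjusted p = 0.0575) or among only the probe sets above the median mean (adjusted p = 0.106). Mitotic cyclins and B-type CDK genes had 0 higher, 0 lower and 8 not called (median -0.29, adjusted p = 0.683 by camera). In all, 5635 probe sets were higher in expanded leaf and 7324 lower. OsMADS58 was higher in expanded leaf by 2.86 (adjusted p = 0.00295) and was not called in the fit of only these groups. Its mean was 4.50 in leaf primordium and 6.03 in the other 2 expanded leaf arrays, against 10.04 in replicate 3.

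Stamens were above both leaf samples in 2490 probe sets and below both in 1154. Both leaf samples lay under the stamens for OsMADS7, OsMADS8, CYCB1-1, MCM3 and MEL1, by 4.69 for MEL1 against leaf primordium and 6.25 against expanded leaf.

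Between stage 2 and stage 6 most early anther genes rose and most meristem and polarity genes fell. BHLH142 rose by 5.20 (SE 0.456, adjusted p = 1.82e-06), GAMYB, a regulator of tapetum development, by 3.22 (SE 0.315), TDR by 2.58 (SE 0.228) and MSP1 by 2.47 (SE 0.324). CYP703A3, a fatty acid hydroxylase of pollen wall formation, rose by 3.16, from 3.03 to 6.20. Early anther genes rose in 4 of 5 cases (adjusted p = 0.00055, but adjusted p = 0.0623 with an estimated correlation). DNA replication genes rose in 5 of 19 cases (7 adjusted over the list alone), RPA70B by 2.15 (adjusted p = 0.00055, but adjusted p = 0.443 with an estimated correlation). RPA32A, among the 5, lost its call when any 1 of 5 arrays was left out and in 1 other setting. Meiosis genes rose in 2 of 7 cases (adjusted p = 0.309). OsMADS6 (-2.06), OsMADS5 (-1.56) and OsMADS1 (-1.50) fell, the last 2 no longer called when any 1 of 5 and of 3 arrays was left out. Late tapetum genes had 1 higher, 1 lower and 3 not called, with median -0.10, mean 0.37 and a test pointing down (adjusted p = 0.912).

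The meristem and polarity genes fell in 3 of 4 cases, OSH1 by a difference of -3.38 and OsYABBY5 of -2.44 (adjusted p = 0.0135, but adjusted p = 0.443 with an estimated correlation). YAB4, also among the 3, lost its call when any 1 of 4 arrays was left out and in 2 other settings. Heat shock proteins fell in 8 of 23 cases and rose in 1, the doubtful HSP26.2 (median -0.16, adjusted p = 0.0456, but adjusted p = 0.531 with an estimated correlation), HSP17.4 by a difference of -3.25. Stage 2 arrays also had the highest mean 3' to 5' difference, 3.28 against 1.67 at stage 6. With it as a covariate HSP17.4, HSP18.1, OSH1, OsYABBY5, OsMADS1, OsMADS5, OsMADS6, PAIR1, MCM7 and MEL1 were no longer called, nor was either list. The heat shock list also lost its call when any 1 of 6 arrays was left out, with quantile normalization, with the mean of the probe sets of each gene and with fry. In the stage 6 minus stage 2 comparison 2521 probe sets were higher and 1984 lower, and 2797 in all with the covariate, of which 1764 were called before in the same direction. Over the 5 stages 4139 probe sets changed, 1777 of them highest at stage 6 and 1495 highest at stage 2; the count was 898 over the stages other than stage 2 (any change across stages).

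**Figure D4:**
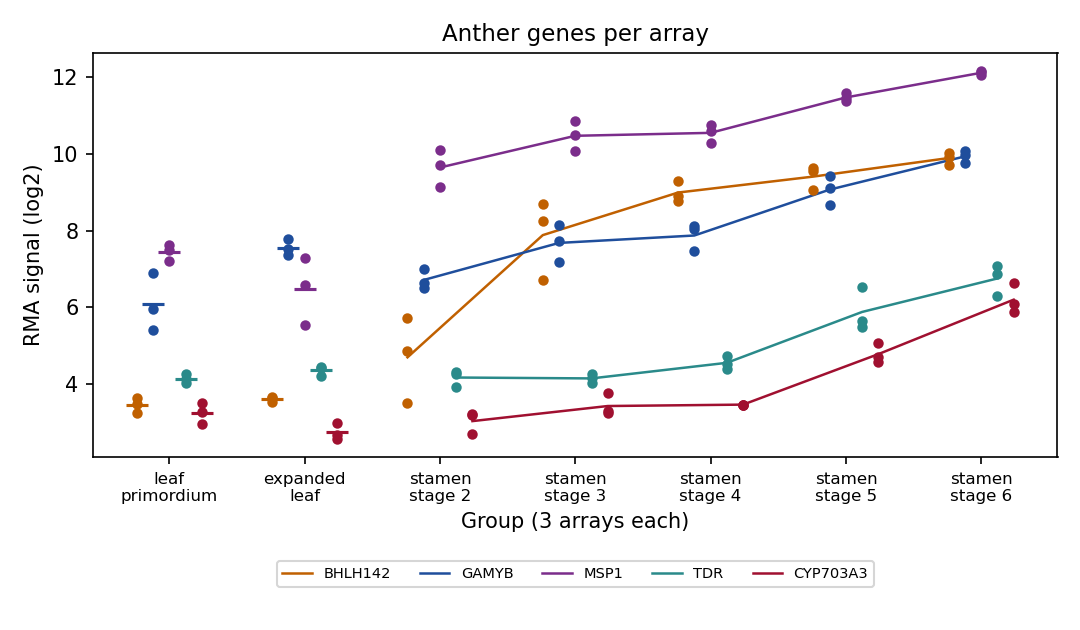
Signal (log2) of 5 anther genes in each array, with lines through the means of the stamen stages and short bars at the leaf means. BHLH142 goes from 4.69 at stage 2 to 9.89 at stage 6, and CYP703A3 from 3.03 to 6.20.

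**Figure D5:**
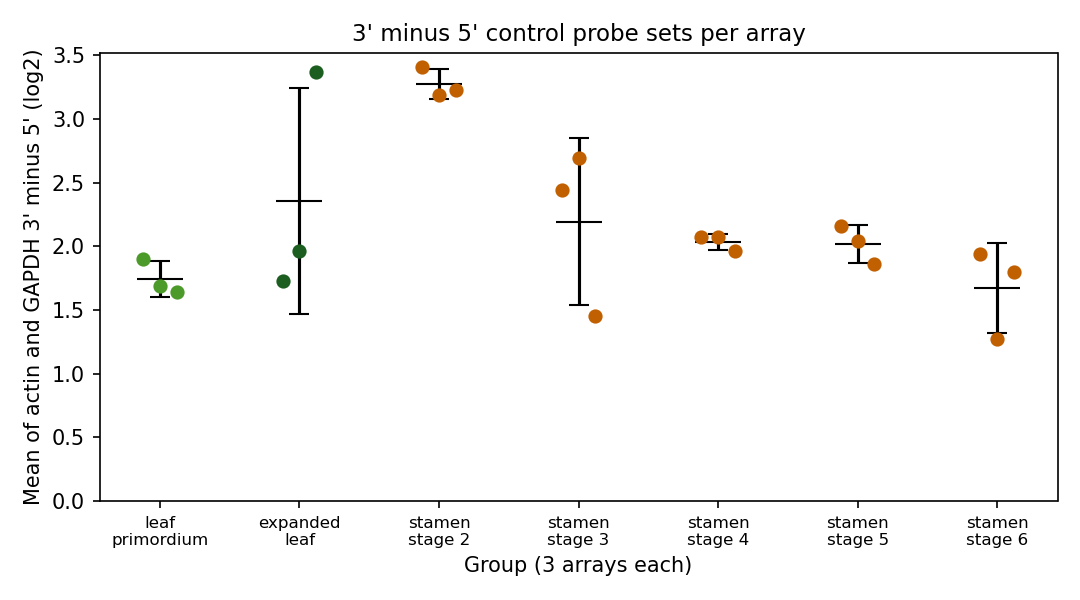
Mean 3' minus 5' log2 difference of the actin and GAPDH control probe sets in each array, with the mean and SD of 3 arrays per group. Stage 2 has a mean of 3.28 and stage 6 of 1.67.

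From stage 2 to stage 3, BHLH142 rose by 3.19 (adjusted p = 0.00107) and SGS3, of the small RNA pathway, by 2.52 on 1 of its probe sets, while the other went from 11.44 to 12.18 and was not called. The homeobox gene WOX11 had a difference of -3.23 and the lipid transfer gene LTP2-B of -3.05. PAIR1, needed for meiotic pairing, rose by 1.26, and its call was lost when any 1 of 9 arrays was left out. BHLH142 lost its call in the fit of only these groups. Of 885 called probe sets 472 were higher and 413 lower. With the 3' to 5' difference as a covariate the count was 219, without stamen stage 3 replicate 3 283, without stage 2 replicate 1 471 and without stage 2 replicate 3 544 (stage 3 minus stage 2).

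From stage 3 to stage 4 there were 4 calls, named after their values were seen: LOC9270116 (2.95, adjusted p = 0.0467), LOC4327363 (1.77), LOC4345161 (1.72) and LOC4342076 (-2.23). The count for stage 4 minus stage 3 was 0 without stage 3 replicate 1, 1 without leaf primordium replicate 1 or 2, stage 4 replicate 2 or 3, or any stage 6 array, 2 without stage 5 replicate 3, and 21 without stage 4 replicate 1.

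From stage 4 to stage 5, TDR (1.33, adjusted p = 0.0416) and CYP703A3 (1.32, adjusted p = 0.0266) rose, as did OsC3H43 (2.76) and the receptor kinase gene FON1 (1.34). Early anther genes had 1 higher (2 adjusted over the list alone) and 4 not called, with a median of 0.92 (adjusted p = 1.28e-05, and 0.0153 with an estimated correlation). DNA replication genes had none called by limma but a median of 0.43 (adjusted p = 1.42e-06, but adjusted p = 0.295 with an estimated correlation and not called with fry). Of 25 calls 21 were higher. The 4 lower ones, named after their values were seen, were LOC4336629 (-1.75), LOC4327905 (-1.68) and 2 probe sets with no gene listed (-1.32 and -1.21). The count for stage 5 minus stage 4 was 16 without any leaf primordium array or stage 2 replicate 1 or 2, 10 without stage 4 replicate 3, 4 without stage 4 replicate 1, 0 without stage 4 replicate 2, stage 5 replicate 1 or stage 5 replicate 2, and 92 without stage 5 replicate 3. The calls ended when any 1 of 17 arrays was left out for TDR, 5 for CYP703A3 and FON1, and 4 for OsC3H43.

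From stage 5 to stage 6 limma called 0 probe sets, with 3336 at an unadjusted p under 0.05. The smallest adjusted p was 0.0518, for CYP703A3 (1.41). Among lists, chloroplast regulators (adjusted p = 0.00684, but adjusted p = 0.0566 with an estimated correlation; 1 gene adjusted over the list alone), DNA replication (adjusted p = 0.00723, but adjusted p = 0.497 with an estimated correlation) and early anther genes (adjusted p = 0.0137, but adjusted p = 0.164 with an estimated correlation) passed. Without stage 5 replicate 3 the DNA replication and early anther lists did not pass, and without stage 6 replicate 2 the early anther list did not. Neither passed with fry, nor the early anther list among only the probe sets above the median mean. The count for stage 6 minus stage 5 was 22 without stage 5 replicate 1, 11 without expanded leaf replicate 2, 8 without stage 3 replicate 1, 3 without stage 6 replicate 2 and 1 without stage 4 replicate 1.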

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

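The tests of 3' bias, those on 1 expanded leaf array and that of scaling on genes of like level were chosen after the result was seen.

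Calls against stage 2 moved with the 3' to 5' difference of actin and GAPDH, which was 3.28 at stage 2 and 2.03 at stage 4, both above every leaf primordium array. With it as a covariate 39.16% of the stage 6 minus stage 2 calls and 18.64% of the stage 3 minus stage 2 calls kept their direction and threshold, under the 50% that had been set as the mark of 3' bias as the whole cause. Their median change went only from 1.43 to 1.23 and from 1.37 to 1.12, while the median SE went from 0.289 to 0.407 and from 0.275 to 0.323, so wider errors ended calls too, and bias and stage cannot be told apart because the difference moves with the stage. The slope on the difference within groups correlated at 0.304 with stage 2 minus stage 6 over the called probe sets, reached in 9 of 100 orders (highest 0.416). A mark of 5 had been set as counting against bias as a part of the cause, but missing that mark excludes nothing, so bias may be a part of it, beside development itself, which was not tested.

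OsMADS58 lay at the stamen level in expanded leaf replicate 3, 4.01 above the other 2 arrays. Stamen RNA in that array would bring the abundant OsMADS7, OsMADS8 and OsMADS16, which moved by -0.55, 0.10 and 0.82, a median of 0.101 where 2 was needed. That value argues against stamen RNA. For 3' bias, stage 2 minus stage 6 was 0.142, which decides nothing because the bias moves with the stage there. The slope of OsMADS58 on the 3' to 5' difference within the stamen stages gives that array a rise of 0.83 (95% bounds 0.03 and 1.64). The upper bound is under 2.01, the mark set against bias as the whole cause. But the slope comes from stamen arrays at 10.27 to 11.32, and it may differ at 5.76 and 6.29, the levels of expanded leaf replicates 1 and 2. Bias in that array stays open, as the whole cause or a part. That array had 207 probe sets 8-fold or more above both other replicates and 39 below, and the other 2 had 86 and 105 above and 47 and 154 below. LEA19, an embryo and seed reserve marker, stood there at 11.27, against 5.15 and 5.72 in replicates 1 and 2. EM, from the same list, differed far less, at 7.12 against 6.31 and 6.23. The remaining markers of that list were not looked at per array. Expression in that leaf sample, other tissue in it and a fault of that array also remain open and were not tested.

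The light reactions genes were low in stamens against expanded leaf and not against leaf primordium. Levels too near the floor to fall in leaf primordium would leave few genes of like level lower in stamens, and 5% or more was to count against that; the median share was 11.2%, but it ran from 2% to 14% over the 10 genes. That mark was wrong, because probe sets of 1 gene differ in level, as those of RCAA1 did in leaf primordium (7.09 and 4.37), so a like level is not a like distance from the floor, and signal over background was not measured. For a shift between arrays, the median stamen minus expanded leaf difference of all genes was 0.102 against -4.60 for the list. That decides nothing by itself, because the normalization sets the array medians alike. Among genes of like mean level 8% (median over the 10 genes) fell by 2.30 or more, so most such genes did not share the list's fall. Quantile normalization also makes the spread of levels alike between arrays, so a shift that it removed cannot be judged. The floor and a shift removed by the normalization stay open, and low expression of these genes in both young organs is an untested hypothesis.

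The difference between the 2 leaf samples is, gene by gene, the difference of the stamen minus leaf values. Its median over the genes was 4.95 for the light reactions, 5.77 for the Calvin cycle and -1.09 for DNA replication, and it was 2.86 for OsMADS58. With an estimated correlation the 3 lists were not called (adjusted p = 0.211, 0.211 and 0.635), and OsMADS58 was not called in the fit of only these groups.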

How the results depend on the processing

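The covariate and the fits without the expanded leaf or stage 2 arrays were chosen after the result was seen. Genes and lists were not run with array weights, without the expanded leaf arrays or without the stage 2 arrays; in the fits they were run in, no called gene changed direction, nor did the test of any called list, though the median of the heat shock list left its side of 0 with the covariate (stage 6 minus stage 2). The counts for stamen minus leaf primordium, stamen minus expanded leaf, expanded leaf minus leaf primordium, stamen above both leaf samples and stamen below both leaf samples stayed within 1.5 times their value except without a fold threshold. Counts between consecutive stages moved most. Where the construction of an alternative does not show it, the cause was not tested. How far signals stood over background was not measured, so changes near it cannot be judged.

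Without a fold threshold the counts were 18201 for stamen minus leaf primordium, 27843 for stamen minus expanded leaf, 20116 for expanded leaf minus leaf primordium, 1592 for stage 3 minus stage 2, 9018 for stage 6 minus stage 2, 6294 for any change across stages, 5254 for stamen above both leaf samples and 2418 for stamen below both leaf samples. At an adjusted p under 0.01 they were 337 for stage 3 minus stage 2, 1 for stage 4 minus stage 3, 6 for stage 5 minus stage 4 and 2567 for any change across stages. Array weights gave 1395 for stage 3 minus stage 2, 123 for stage 4 minus stage 3, 176 for stage 5 minus stage 4, 72 for stage 6 minus stage 5 and 6408 for any change across stages. Fits of only the groups compared gave 452 for stage 3 minus stage 2, 0 for stage 4 minus stage 3 and 0 for stage 5 minus stage 4. Both filters on dim probe sets gave 4 for stage 5 minus stage 4, and the trend and robust prior gave 4 for stage 6 minus stage 5. The replicate block ended the call of the heat shock list (stage 6 minus stage 2) and gave 2 for stage 4 minus stage 3, 15 for stage 5 minus stage 4 and 1 for stage 6 minus stage 5. Arrays of the same number did not pair: the median correlation of their residuals was 0.02 over 63 pairs and -0.008 over 126 other pairs.

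With the 3' to 5' covariate the counts were 219 for stage 3 minus stage 2, 2 for stage 6 minus stage 5, 2797 for stage 6 minus stage 2 and 2124 for any change across stages. Without the expanded leaf arrays they were 1363 for stage 3 minus stage 2, 9 for stage 4 minus stage 3 and 22 for stage 6 minus stage 5. Without the stage 2 arrays any change across stages gave 898, with a stage fewer to differ. The gene list tests had 31 calls over the 8 comparisons, 5 with an estimated correlation and 58 with fry, which asks another question. The 5 calls of the photosynthesis light reactions list per stage became 0 with an estimated correlation, and the 10 of OsMADS58 per group became 5 in fits of only the groups compared.

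Leaving out each array in turn gave 283 to 1176 for stage 3 minus stage 2 (lowest without stage 3 replicate 3, highest without expanded leaf replicate 3), 0 to 21 for stage 4 minus stage 3, 0 to 92 for stage 5 minus stage 4 and 0 to 22 for stage 6 minus stage 5. It gave 3667 to 4852 for stage 6 minus stage 2 and 3037 to 5040 for any change across stages. Among 522 values of named genes, 22 lost their call in fits of only the groups compared, 32 with the covariate and 35 when some array was left out.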

Other observations

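The genes in the next paragraph and their comparison were chosen after the result was seen, and the splits of the arrays were not.

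Of 19 genes of the small RNA pathway, 10 were higher in stamens than in leaf primordium, 1 was lower and 8 were not called; against expanded leaf 13 were higher, 1 lower and 5 not called. Between stage 2 and stage 6, 6 rose, 2 fell and 11 were not called, while the 3' to 5' difference went from 3.28 to 1.67. MEL1, among the 6, was not called with that difference as a covariate. The Argonaute genes AGO1D and MEL1 were high: AGO1D had a mean of 9.92 in leaf primordium, 6.07 in expanded leaf and 13.57 at stage 6, and MEL1 of 6.86, 5.31 and 12.48. SHL2, which takes part in the making of trans-acting small RNA, was higher in stamens by 3.55 against leaf primordium and 3.03 against expanded leaf. RDR2, an RNA-dependent RNA polymerase, was lower, at -3.90 and -1.04. Between stage 2 and stage 6 AGO18 had a difference of -3.12 and DCL4 of 1.44. SGS3 rose on 2 probe sets that differ in size, from 9.67 to 13.29 and from 11.44 to 12.91.

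Splits of the same arrays tested whether chance could give as many calls. With the stamen arrays as 1 group, 1 of 100 splits of 18 arrays, the real one, gave as many as its 7869 calls for stamen against leaf primordium (highest other 7), and 1 of 100 gave as many as 13152 for stamen against expanded leaf (highest other 5585, which points to structure among the samples). The same held for the 4139 calls over the stages (1 of 100, highest other 1719). It also held for the 2288 above both leaf samples (1 of 100, highest other 0) and the 1088 below both (1 of 100, highest other 0). This excludes only a random labelling of the arrays as the source of these 5 counts. Most random splits mix arrays of different groups, which widens the spread and leaves few calls. The splits cannot exclude a bias that moves with the group, such as the 3' to 5' difference, and test no single call. For the 9 gene lists against expanded leaf only the real split gave as many (1 of 100), but another gave 8, a narrow margin. Against leaf primordium, chance cannot be excluded as the source of the number of lists called, 7 (5 of 100, highest other 8). Both list counts come from fits with the stamen arrays as 1 group, and neither tests a single list.

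Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real value and the highest other were 12959 and 81 for expanded leaf against leaf primordium (1 of 10), 885 and 1 for stage 3 against 2 (1 of 10), 4 and 0 for stage 4 against 3 (1 of 10), 25 and 0 for stage 5 against 4 (1 of 10), 0 and 0 for stage 6 against 5 (10 of 10) and 4505 and 1 for stage 6 against 2 (1 of 10). For gene lists they were 3 and 5 for expanded leaf against leaf primordium (5 of 10) and 4 and 8 for stage 6 against 2 (3 of 10).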
